A study of Caenorhabditis elegans with 4 samples.

How the data were processed

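Gene expression of Caenorhabditis elegans was measured on 4 spotted arrays that each carried 2 labelled RNA samples. Per the labels, channel 1 of every array held RNA of a wild-type mixed reference and channel 2 held mRNA of glp-4 adults, from preps numbered 1 to 4. What was mixed in the reference, the glp-4 allele, the growth temperature and the age of the adults are not given in the sources used here. The number 1 to 4 names the prep on its array, and the 4 arrays formed the only group. Nothing states whether the preps came from separate worm cultures, so p-values measure the spread between these 4 preps, which may be technical.

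The deposited values are log2 ratios of the 2 channels, 1 column per array over 21632 spots. The scale was settled from the values: on every array, 100% of the values below -2 were the log2 of a ratio that is a whole multiple of 0.001, within 1e-06. The scanner, the background correction, the normalization, the spot filter and the dyes of both channels are not given in the sources used here. The array medians were 0.0759 for prep 1, -0.0454 for prep 2, -0.0695 for prep 3 and -0.0306 for prep 4, and the SDs of all log2 values were 0.871, 1.21, 0.907 and 1.06 in that order. All 4 medians lay within 0.1 of 0, the limit set before the data were examined, so the deposited values were used without further centring. The centring method of the authors stays unknown. Spots without a value numbered 118 on prep 1, 547 on prep 2, 304 on prep 3 and 486 on prep 4. The direction of the ratio, glp-4 adults over reference, is likely only: each array is described as glp-4 against reference, with the reference in channel 1 and the glp-4 RNA in channel 2, and no dye is named. No array was turned on its values, and all pairs of arrays correlated positively. No array had its dyes exchanged as far as the labels tell, so a dye bias of a spot would not cancel in the mean. The signal over background behind each spot is unknown, and the number of arrays limits the precision.

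Gene names came from the annotation of the array platform. It gave 1 gene for 16450 of the 21632 spotted probes (76.0%) and several genes for 247, and it did not list 4935 probes, which are unnamed here. Of the named probes, 16360 matched a gene of the RefSeq table of assembly WBcel235 by gene number, which changed 0 symbols, and the other 90 kept the name of the annotation. That table was used only for names, gene types, the X chromosome and which genes neighbour each other, because no genome build is named for the arrays. Probes of 1 gene were averaged on each array, which left 20140 features, 14958 of them named genes, and 1448 genes had several probes. A probe with several genes or none remained a feature of its own without a name. The gene glp-4 had no probe of its own under its name, so its level was not analysed here.

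The comparison tested the mean log2 ratio of the 4 preps against 0, two-sided, with limma 3.58.1 in R 4.3.3 (lmFit with an intercept only, then eBayes), for features with a value on at least 3 arrays. Benjamini-Hochberg adjusted p under 0.05 over all 19981 tested features was the threshold. Because the reference RNA is the only wild-type RNA, the test leaves out the spread between wild-type samples. Errors after ± are SDs over the preps. An exact two-sided permutation of signs over 4 preps cannot give a p below 0.125, so no such test was used for single values. Joining of tables used Python 3.11.15 with pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

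Before the data were examined, 24 gene lists were fixed: germ granule and germline RNA regulation, small RNA pathways of the germline, meiotic chromosome pairing and recombination, oocyte and maternal genes, sperm genes other than major sperm proteins, major sperm proteins, DNA replication and mitosis, early embryo zygotic transcription, yolk proteins, numbered cuticle collagens, furrow and other body shape collagens, moulting, muscle, intestine, neurons, FMRFamide-like and neuropeptide-like peptides, small heat shock proteins and stress chaperones, DAF-16 targets and germline-less longevity, antimicrobial effectors, fatty acid synthesis and desaturation, cytosolic ribosomal proteins, oxidative phosphorylation, the proteasome, and histones. Numbered families such as collagens, major sperm proteins and histones took every gene of that symbol on the array. A list of X-linked genes, planned for the case that chromosomes could be named, took the chromosome from the RefSeq table, and was run only after the other results were seen. Each of these 25 lists with at least 4 tested members, 24 in all, was compared with all other features by camera of limma with a preset correlation between genes of 0.01, two-sided, with Benjamini-Hochberg adjustment over the 24 lists. The moderated statistics entered camera as z scores (cameraPR), because camera itself takes no missing values. The same test with the correlation estimated from the arrays, and fry, used the 19100 features with a value on all 4 arrays. With an estimated correlation, camera takes its degrees of freedom from the 4 arrays and not from the number of features. Its p is therefore higher even at the same correlation.

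The genes named in the text followed a rule set in advance. It took the 12 highest and the 12 lowest mean log2 ratios among genes with a symbol that passed the threshold with the same sign on every measured array, at most 2 per numbered family. It also took up to 4 members per list past the threshold with the largest absolute mean, or up to 2 members by size where fewer than 2 passed, and all yolk protein genes. Genes outside the rule are marked as such.

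The fit and the list test were tested on simulated data of 19981 features with the spread of these arrays, 200 of them changed, 50 at each size. The test recovered 0% of changes of 0.5 on the log2 scale, 10% of changes of 1, 92% of changes of 2 and 98% of changes of 3, with 6 false calls among 106. Of 9 lists shifted by 1 on the log2 scale, the X-linked list among them, 9 were called, as was 1 of 5 lists without a shift or a shared member. The simulated data held fewer changed features than passed the threshold in the real data. The adjusted threshold was therefore stricter there, and the recovered shares do not describe the test of the real data. Simulated features were also drawn independently of each other, while the correlation estimated within the real body shape collagens was 0.696. The list result therefore gives no error rate for lists of correlated genes.

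Alternatives covered the number of arrays required, the centring and scaling of arrays, the variance model, robust and weighted fits, single probes in place of averages, other thresholds, other list tests and leaving out each prep in turn. For the scaling between arrays the median absolute values of the arrays were made equal. Blocks for the arrays that share a title prefix or a title date could not be fitted.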

Results

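The data were 4 arrays, each with mRNA of glp-4 adults against the same wild-type mixed reference RNA, and 21632 spots per array. The gene glp-4 encodes a valyl-tRNA synthetase, and worms that carry its temperature-sensitive mutation and grow at the restrictive temperature become adults with hardly any germ cells. The labels give no temperature and do not state what was mixed in the reference. The comparison implied by the design was which transcripts made up a larger or smaller share of the RNA in glp-4 adults than in the reference. Because the arrays came centred, each ratio is relative to the other transcripts on its array. A higher ratio therefore does not show that the amount of a transcript per worm or per cell rose, and a lower one does not show that it fell. Whether the higher lists and families reflect a smaller share of other transcripts was not tested. Genotype, age and anything else that differed between the adults and the reference enter the same ratio. Over the features measured on both arrays of a pair, the log2 ratios of 2 preps had Pearson correlations between 0.727 (preps 1 and 3) and 0.796 (preps 3 and 4), with a median of 0.755. These are correlations across genes, which are not independent replicates. The arrays of preps 3 and 4 share a title date and those of preps 1 and 2 a title prefix, so the preps may not be equally separate. Every signed value follows the likely direction, glp-4 adults over reference, on the basis of the array descriptions and the channel order; no dye was named, and in the opposite direction every sign would turn.

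In glp-4 adults, the lists of oocyte, major sperm protein, meiosis and cell division genes were lower than in the reference, and those of intestinal, numbered collagen and muscle genes were higher, in camera of limma with a preset correlation. With an estimated correlation, 0 of the 24 lists tested passed, and the lowest adjusted p was 0.0708 with an estimated correlation. That setting has only the degrees of freedom of the 4 arrays, so failing it does not show that a list did not differ. Of 19981 features tested with limma, 7577 (37.9%) passed the threshold, 3403 with a higher and 4174 with a lower ratio in glp-4 adults. At least 2-fold differences made up 1565 of the higher and 2158 of the lower features, and at least 8-fold differences 110 and 138. Of the features past the threshold, 7442 had the same sign on every measured array, and 2717 of the higher and 3300 of the lower ones were named genes. Without prep 4, the higher features numbered 2073. Pseudogenes, chemoreceptor genes and F-box genes, which are mostly weakly expressed, had a median log2 ratio of 0.32 over 1842 features and made up 358 of the higher and 108 of the lower features, so small positive ratios have to be read beside that value.

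The 12 lowest named genes were led by genes of oocytes and the eggshell. The chondroitin proteoglycan gene cpg-2 (B0280.5) had a log2 ratio of -4.84 ± 0.23 (28.6-fold lower, SD, n = 4 preps), and cpg-1 (C07G2.1) one of -4.38 ± 0.37. The zinc-finger genes pos-1 (F52E1.1) and oma-2 (ZC513.6), which act in the embryo and in oocyte maturation, had values of -4.66 ± 0.28 and -4.60 ± 0.60. The RNA-binding protein gene puf-5 (F54C9.8) had -4.18 ± 0.31, the Y-box gene cey-3 (M01E11.5) -4.43 ± 0.38 on 3 arrays and sip-1 (F43D9.4), a small heat shock protein gene, -4.28 ± 0.43. The remaining members were clec-87 (C25A1.8, -4.47 ± 0.45), trcs-1 (F27C8.6, -4.40 ± 0.33), nasp-2 (C50B6.2, -4.40 ± 0.36), gln-6 (C28D4.3, -4.40 ± 0.33) and mesp-1 (C28C12.2, -4.24 ± 0.42). The highest named genes included genes known for their response to pathogens: irg-5 (F35E12.5) had a log2 ratio of 6.69 ± 0.65 (103-fold higher, n = 4 preps) and irg-4 (F08G5.6) one of 5.25 ± 0.99. The genes dod-21 (C32H11.10), cld-1 (C32H11.9) and dod-24 (C32H11.12) had 6.40 ± 0.94, 6.27 ± 0.92 and 5.15 ± 0.80. The UDP-glucuronosyltransferase genes ugt-13 (H23N18.1) and ugt-63 (C04F5.7) had 5.41 ± 1.41 and 5.14 ± 1.22, the latter 5.74 without prep 1. The others were pud-2.1 (F15E11.1, 4.90 ± 0.88), pud-4 (F15E11.12, 4.77 ± 0.63), mbug-1 (F55G11.4, 4.75 ± 0.84), the lectin gene clec-52 (B0218.8, 4.65 ± 0.33) and the collagen gene col-7 (C15A11.5, 4.60 ± 1.06). In limma, the adjusted p of these 24 genes lay between 7.31e-05 (irg-5) and 0.000355 (ugt-13).

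**Figure D1:**
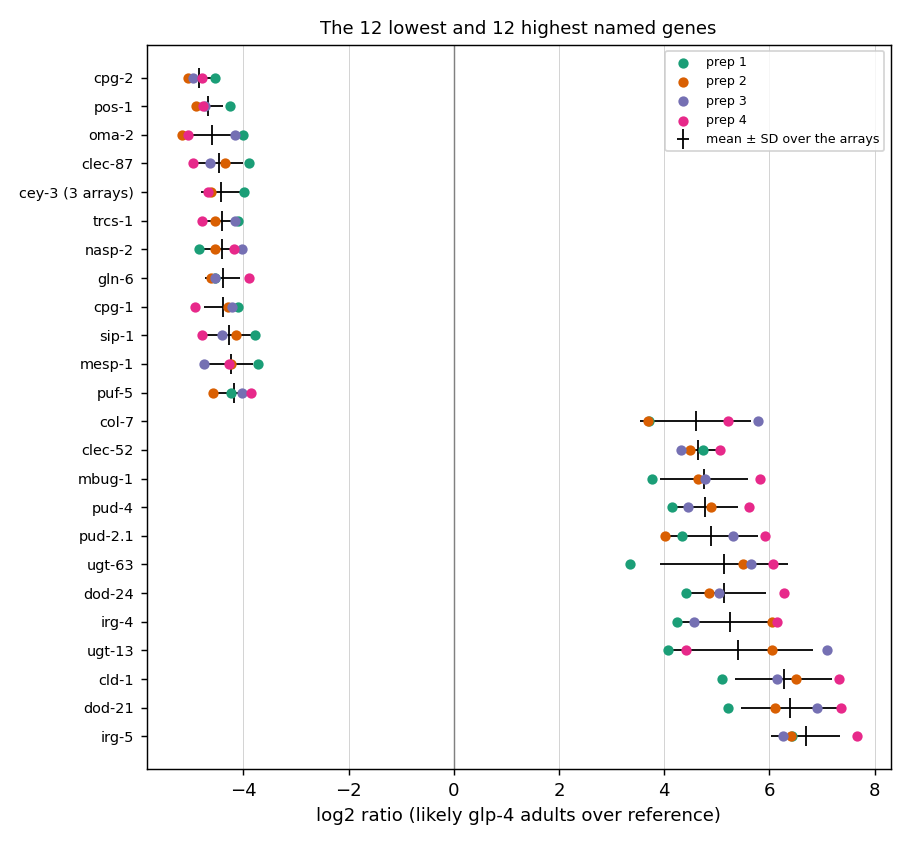
Log2 ratios on the horizontal axis (likely glp-4 adults over reference) of the 12 lowest and 12 highest named genes, with a coloured point for each of the 4 preps, a tick for the mean and a bar for ± 1 SD over the preps measured. The means of the lowest genes run from -4.84 for cpg-2 to -4.18 for puf-5, and those of the highest from 4.60 for col-7 to 6.69 for irg-5.

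Lists of oocyte, meiosis and other germline genes were lower in camera. Of 35 oocyte and maternal genes, 31 were lower, 0 were higher and 4 did not pass, with a mean over the list of -2.87 ± 0.31, an adjusted p of 6.55e-18 in camera of limma and an adjusted p of 0.212 with an estimated correlation. Besides cpg-2, pos-1 and oma-2, this list held trcs-1. All 25 tested genes of meiotic chromosome pairing and recombination were lower (mean -2.11 ± 0.40, adjusted p = 1.81e-13, adjusted p = 0.212 with an estimated correlation), among them the chromosome axis genes him-3 (-3.42 ± 0.52) and htp-1 (-3.07 ± 0.58) and the pairing-centre genes zim-1 (-3.34 ± 0.29) and zim-2 (-3.32 ± 0.94). Of 28 genes of germ granules and germline RNA regulation, 25 were lower and 0 higher (mean -1.78 ± 0.34, adjusted p = 5.63e-13, adjusted p = 0.212 with an estimated correlation). Examples were nos-2, which acts in primordial germ cells (-3.31 ± 0.37), the translational repressor gld-1 (-2.99 ± 0.63) and cey-2 (-2.88 ± 1.07). Of 21 genes of germline small RNA pathways, 15 were lower and 0 higher (mean -1.27 ± 0.21, adjusted p = 1.90e-07, adjusted p = 0.212 with an estimated correlation), with the Argonaute genes wago-1 (-3.80 ± 0.25), hrde-1 (-2.83 ± 0.69) and prg-2 (-2.11 ± 0.26) and the piRNA pathway gene tost-1 (-3.42 ± 0.41). Adjusted over the list alone, 31, 25, 27 and 17 genes of these lists were lower, in the order given.

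Sperm genes were tested as 2 lists. Of 30 major sperm protein genes, which encode the motility and signalling protein of nematode sperm, 29 were lower and 0 higher, with a mean of -2.94 ± 0.34 (7.68-fold lower), an adjusted p of 1.91e-18 in camera and an adjusted p of 0.212 with an estimated correlation. The lowest were msp-77 (-3.83 ± 0.44), msp-33 (-3.74 ± 0.58), msp-113 (-3.73 ± 0.60) and msp-36 (-3.62 ± 0.53). These genes are near-identical in sequence, so a spot can report several of them, and the 30 values are not independent. Of 43 other sperm genes, 18 were lower, 3 were higher and 22 did not pass (mean -0.48 ± 0.14, adjusted p = 0.000942, adjusted p = 0.355 with an estimated correlation). Among these, nspd-5 (-1.79 ± 0.28), nspd-6 (-1.70 ± 0.36) and nspd-2 (-1.63 ± 0.50) were lower and ssp-37 was higher (1.72 ± 0.53). Of 24 tested genes of the spe family, a group chosen after seeing the data, 1 was lower and 0 were higher (median -0.04, adjusted p = 0.897 in camera). The counts adjusted over the list alone were similar: 29 major sperm protein genes were lower, and of the other sperm genes 19 were lower and 3 higher. The difference between both lists was not tested.

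Genes of DNA replication and mitosis were lower: of 43 tested, 38 were lower and 0 higher, with a mean of -1.99 ± 0.28, an adjusted p of 6.05e-18 in camera and an adjusted p of 0.212 with an estimated correlation. The mitotic cyclin gene cyb-3 (-3.74 ± 0.58), the cyclin-dependent kinase gene cdk-1 (-3.37 ± 0.23), the ribonucleotide reductase gene rnr-2 (-3.54 ± 0.24) and the replication helicase gene mcm-5 (-3.46 ± 0.90) were the furthest from 0. The count adjusted over the list alone was also 38. Of 31 proteasome genes, 25 were lower, 0 were higher and 6 did not pass (mean -0.60 ± 0.14, 1.52-fold lower, adjusted p = 3.12e-07, adjusted p = 0.332 with an estimated correlation), and 25 were lower when adjusted over the list alone. The subunits rpt-1 (-0.93 ± 0.33), pas-5 (-0.92 ± 0.36), rpn-3 (-0.91 ± 0.16) and rpn-9 (-0.90 ± 0.14) lay close together.

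Of 36 intestinal genes tested, 31 were higher, 1 was lower and 4 did not pass, with a mean of 1.49 ± 0.10 (2.80-fold higher, n = 4 preps), an adjusted p of 5.63e-13 in camera and an adjusted p of 0.0708 with an estimated correlation. The cathepsin B-like protease gene cpr-5 (3.52 ± 0.57), the P-glycoprotein gene pgp-1 (3.20 ± 0.24), the peptide transporter gene pept-1 (2.68 ± 0.38) and the sodium-proton exchanger gene nhx-2 (2.61 ± 0.42) were highest. The exception was ftn-1, a ferritin gene (-2.01 ± 0.34), named after its value was seen. In the intestine, 31 were higher and 1 lower when adjusted over the list alone. Of 42 muscle genes, 19 were higher, 1 was lower and 22 did not pass (mean 0.61 ± 0.34, adjusted p = 2.61e-05, adjusted p = 0.434 with an estimated correlation). The troponin genes tnt-2 (2.04 ± 0.18) and unc-27 (1.89 ± 0.26), dim-1 (1.73 ± 0.67) and clik-1 (1.63 ± 0.19) led, and the lower member, named after its value was seen, was tnc-2 (-0.57 ± 0.36). For muscle, 20 were higher and 1 lower when adjusted over the list alone.

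Of the yolk protein genes, vit-6 was higher (1.19 ± 0.66, adjusted p = 0.0106 in limma), while vit-5 had a value of 0.45 ± 0.81 and vit-2 one of 0.08 ± 0.68, neither past the threshold. Without prep 1 the value of vit-2 was -0.19, and without prep 3 it was -0.02. With 3 measured members the list was too small for the list test. Its mean was 0.58 ± 0.38, and vit-6 was also the member that passed when adjusted over the list alone. Of 27 genes of fatty acid synthesis and desaturation, 15 were higher, 3 lower and 9 did not pass (mean 0.53 ± 0.19, adjusted p = 0.00273, adjusted p = 0.293 with an estimated correlation), and 16 were higher and 4 lower when adjusted over the list alone. The acyl-CoA synthetase gene acs-1 (2.52 ± 0.55), acdh-1 (2.14 ± 0.98) and pmt-2, which acts in phosphatidylcholine synthesis (1.84 ± 0.33), were higher, and the elongase gene elo-4 was lower (-2.68 ± 0.07, 3 arrays).

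Cuticle genes went both ways. Of 134 numbered collagen genes, 65 were higher, 29 lower and 40 did not pass, with a mean of 0.88 ± 0.42, an adjusted p of 2.40e-05 in camera and an adjusted p of 0.462 with an estimated correlation. Beside col-7, col-139 (4.47 ± 0.75), col-142 (4.41 ± 0.95) and col-62 (4.22 ± 0.83) were highest, and 70 were higher and 31 lower when adjusted over the list alone. Of 18 furrow and other body shape collagens, 3 were higher, 7 lower and 8 did not pass, and the list did not pass (mean -0.29 ± 0.59, adjusted p = 0.266). Its members dpy-17 (-2.72 ± 0.59), rol-8 (-2.61 ± 0.57) and dpy-7 (-1.62 ± 0.49) were lower and bli-2 was higher (2.64 ± 0.76). Adjusted over the list alone, 3 were higher and 7 lower. The list mean was 0.41 on prep 3 and below 0 on the other preps, lowest on prep 1. Of 38 moulting genes, 6 were higher, 15 lower and 17 did not pass, without a call for the list (mean -0.29 ± 0.28, adjusted p = 0.179). Without prep 3 the moulting list passed at an adjusted p of 0.0365, the lowest of its alternatives, which ranged up to 0.801. The hedgehog-related gene grd-3 was higher (1.92 ± 0.25) and wrt-10 (-1.83 ± 0.57), wrt-1 (-1.53 ± 0.90) and the cuticle protein gene noah-1 (-1.56 ± 0.57) were lower, with 7 higher and 16 lower members when adjusted over the list alone.

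**Figure D2:**
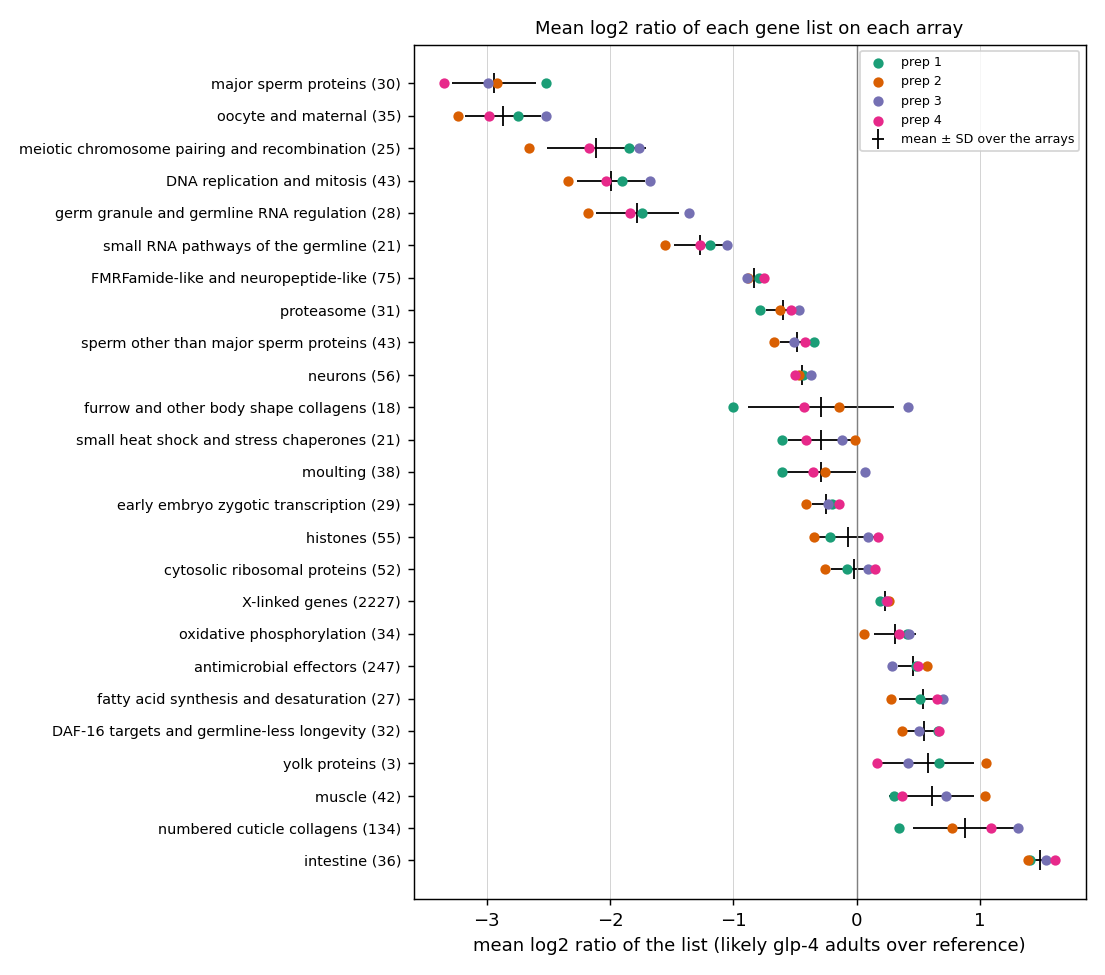
Mean log2 ratio of each of the 25 gene lists on the horizontal axis (likely glp-4 adults over reference), with a coloured point per prep, a tick for the mean and a bar for ± 1 SD over the 4 preps; the number of tested genes stands in parentheses. Major sperm proteins have the lowest mean (-2.94) and intestinal genes the highest (1.49), and the body shape collagens spread most between preps (SD 0.59).

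Neuropeptide and neuron lists were lower in camera. Of 75 neuropeptide genes, 49 were lower, 3 higher and 23 did not pass, with a mean of -0.83 ± 0.07 (1.78-fold lower), an adjusted p of 6.84e-11 in camera and an adjusted p of 0.0708 with an estimated correlation. The lowest were nlp-14 (-3.14 ± 2.45), nlp-32 (-2.31 ± 0.29), nlp-12 (-2.22 ± 0.28) and nlp-55 (4.28-fold lower), and the wide spread of nlp-14 came from a value of -6.80 on prep 3, without which its mean was -1.92. Of 56 neuron genes, 24 were lower, 1 was higher and 31 did not pass (mean -0.44 ± 0.05, adjusted p = 0.000683, adjusted p = 0.212 with an estimated correlation). Lower members that make or process neuropeptides included egl-3 (-1.57 ± 0.25) and pgal-1 (-1.58 ± 0.23). The synaptotagmin gene snt-1 had -1.95 ± 1.83, with an adjusted p of 0.0431 in limma that rose to 0.0741 without prep 1 and 0.0880 without prep 2, over a range of 0.0271 to 0.0880 for its alternatives. Its value on prep 4 was -4.61, against -1.44 to -0.43 on the other preps, and without prep 4 its mean was -1.06 (adjusted p = 0.0271). When adjusted over the list alone, 50 neuropeptide genes were lower and 3 higher, and 24 neuron genes were lower and 4 higher.

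Genes in the lists for stress, defence and long life split within their lists. The antimicrobial list was taken by gene symbol, so membership does not show a role in defence. Of 247 genes of the antimicrobial list, 73 were higher, 20 lower and 154 did not pass (mean 0.46 ± 0.12, adjusted p = 8.40e-06, adjusted p = 0.212 with an estimated correlation). The counts were the same when adjusted over the list alone. C-type lectin genes made up 202 of them, with clec-52 among the highest and clec-87, clec-91 (-4.10 ± 0.74) and clec-88 (-3.87 ± 0.55) among the lowest genes. Without the lectin genes, a choice made after seeing the data, the list did not pass (45 genes, mean 0.30, adjusted p = 0.0889). The median of the whole antimicrobial list was 0.39, beside 0.32 for pseudogenes, chemoreceptor genes and F-box genes. A part of dim spots in the mean of this list was not tested. Of 32 DAF-16 and longevity genes, 12 were higher, 6 lower and 14 did not pass (mean 0.55 ± 0.14, adjusted p = 0.0436, adjusted p = 0.293 with an estimated correlation), and 13 were higher and 6 lower when adjusted over the list alone. The highest were dod-24, dod-17 (3.48 ± 1.24), the steroid hormone synthesis gene daf-36 (2.81 ± 0.38) and the glutathione transferase gene gst-4 (2.54 ± 0.70). The genes dod-17, dod-22 and dod-24 are known as genes that DAF-16 lowers, and without them, a choice made after seeing the data, the list did not pass (29 genes, mean 0.27, adjusted p = 0.193). It also did not pass without prep 1 (adjusted p = 0.0804) or with ranks (adjusted p = 0.0588), over a range of 0.0115 to 0.293 for its alternatives set in advance. Of 21 heat shock and chaperone genes, 4 were higher, 8 lower and 9 did not pass, and the list did not pass (mean -0.29 ± 0.27, median 0.06, tested downwards, adjusted p = 0.601). Next to sip-1, hsp-12.6 was lower (-3.89 ± 0.68), while hsp-3 (1.68 ± 0.32) and hsp-17 (1.44 ± 0.68, 3 arrays) were higher, with 5 higher and 8 lower members when adjusted over the list alone.

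Among genes of general cell functions, oxidative phosphorylation had 15 higher, 3 lower and 16 members not past the threshold of 34 (mean 0.31 ± 0.17, adjusted p = 0.000313, adjusted p = 0.442 with an estimated correlation), and 19 higher and 3 lower when adjusted over the list alone. Its lower members were ucr-2.3 (-2.90 ± 0.12), asb-1 (-2.14 ± 0.19) and cox-11 (-1.06 ± 0.16), while ucr-2.2, which encodes the same kind of complex III subunit as ucr-2.3, was higher (1.27 ± 0.13). Of 52 cytosolic ribosomal protein genes, 50 did not pass, rpl-11.1 was lower (-2.77 ± 0.03) and its sibling rpl-11.2 higher (0.66 ± 0.09, adjusted p = 0.0109, but 0.0506 without prep 4, the highest of its alternatives). The mean of that list was -0.02 ± 0.18, its median was 0.02 and its test ran upwards (adjusted p = 0.677). Adjusted over the list alone, 0 were higher and 1 was lower. Of 55 histone genes, 6 were higher, 7 lower and 42 did not pass (mean -0.07 ± 0.25, adjusted p = 0.663), with 2 higher and 4 lower when adjusted over the list alone. The linker histone gene his-24 (4.60-fold lower) and his-74 (-2.08 ± 0.36, 3 arrays) were lower and his-44 was higher (0.96 ± 0.35). The value of his-38 (0.85 ± 0.72, adjusted p = 0.0456) averaged probes at 0.22 and 1.48 and lost its call in 6 of 9 alternatives: without prep 2 (0.0826), prep 3 (0.149) or prep 4 (0.156), with scaling between arrays (0.0535), quantile scaling (0.0627) and a robust fit (0.0969), over a range of 0.0164 to 0.156. Of 29 genes of early embryonic transcription, 4 were higher, 8 lower and 17 did not pass, and the list did not pass (mean -0.25 ± 0.12, adjusted p = 0.242), with the same counts when adjusted over the list alone. The embryonic transcription factor genes pal-1 (-1.99 ± 0.47) and lin-26 (-1.28 ± 0.43) and the gene lir-1 (-1.76 ± 0.43) were lower, and sdz-27 was higher (2.02 ± 0.32).

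Of 2227 genes on the X chromosome, 587 were higher, 263 lower and 1377 did not pass, with a mean of 0.23 ± 0.03 (1.18-fold higher), an adjusted p of 0.000769 in camera and an adjusted p of 0.129 with an estimated correlation. This planned list was run only after the results of the other lists were seen. The furthest from 0 were hrg-11.2 (4.08 ± 0.52), ttr-14 (3.90 ± 0.46) and the collagen genes col-19 (3.74 ± 0.64) and col-179 (3.62 ± 0.32), and 588 were higher and 263 lower when adjusted over the list alone. The median was 0.18, below the median of 0.32 of pseudogenes, chemoreceptor genes and F-box genes, and a part of dim spots in the mean of this list was not tested.

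Of the 24 lists tested, 18 passed in camera with the preset correlation, 8 with higher and 10 with lower ratios, and 0 passed with an estimated correlation, where 4 lists had an unadjusted p under 0.05 and the lowest adjusted p was 0.0708. Fry, which asks whether the genes of a list move one way and not whether they differ from other genes, called 20 lists. Among 1441 genes with several tested probes, 351 had probes of opposite sign and 10 had probes called in opposite directions, none of them named here.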

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

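Of the tests weighed in this part, those on dilution of neuronal RNA, on the share of neurons and all 3 on collagen and moulting genes were chosen after the results were seen. Of 131 named genes and lists with values on all 4 preps (106 genes and 25 list means), 6 had 1 prep far from the other 3, and about 1 in 20 would by chance. The log2 ratio of irg-5 was 7.66 on prep 4 against 6.25 to 6.44 on the other preps. That of gln-6 was -3.90 on prep 4 against -4.61 to -4.54, and that of nos-2 was -3.86 on prep 4 against -3.18 to -3.05. For tost-1, prep 3 had -2.81 against -3.66 to -3.59, and for zim-1, prep 2 had -3.78 against -3.21 to -3.16. For nlp-14, prep 3 had -6.80 against -2.27 to -1.62.

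Neuropeptide genes had a median log2 ratio of -0.91. A dye bias that lowers dim spots is argued against by annotated pseudogenes, most of them weakly expressed: their median was 0.247 (95% bootstrap interval 0.204 to 0.280, 551 features). An even dilution of neuronal RNA by other tissue would move the neuron list without shared members alike. That list lay above the neuropeptide list on each of the 4 preps, by a mean difference of -0.418 ± 0.118 for neuropeptides minus neurons. The test takes both lists as read from neurons alone and free of the offset of dim spots that stays open below. It therefore cannot decide, and even dilution stays open. A biological difference between the adults and the mixed reference, in age or genotype, stays open and was not tested.

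Some families of weakly expressed genes had small positive ratios: the median over 1110 chemoreceptor genes was 0.37 (95% interval 0.345 to 0.399), with 208 higher and 26 lower. If an offset of dim spots were the source, F-box genes, mostly weakly expressed and not neuronal, should share it. Their median was 0.138 (95% interval 0.0326 to 0.219, 257 genes), on both sides of the bound of 0.1 set for the test, so this offset stays open. The F-box families differed: the median was 0.314 over 133 fbxa genes, 0.034 over 84 fbxb genes and 0.030 over 40 fbxc genes. A larger share of neurons in glp-4 adults would raise the neuron list, whose mean was -0.443 ± 0.054. That value argues against a larger share only as far as the list is read from neurons alone. It was also known before the test was chosen. Pseudogenes, chemoreceptor and F-box genes together had 358 higher and 108 lower of 1842 features, against 3045 higher and 4066 lower of the 18139 others.

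Body shape collagens and moulting genes differed between preps: 28 of 55 (50.9%, exact 95% interval 37.1% to 64.6% with genes taken as independent) were highest on prep 3 and lowest on prep 1, as were 42.9% of 21 dnj genes (DnaJ-like chaperones), 38.5% of 130 col genes and 29.4% of 17 innexin genes. A shift of whole arrays stays open: the pattern was read from these genes, and the arrays came centred, so that 8.61% of the 19100 features measured on all 4 preps, near the 8.33% of equal chances, cannot speak against it. The share among moulting genes that are not collagens, 16 of 37 (43.2%), cannot speak for preps taken at different times relative to a moult. The reason is that the pattern was read from these genes. In moult-related families outside both lists, a test chosen after that one was found void, it was 15 of 84 (17.9%), between the median (6.25%) and the 95th percentile (26.8%) of 97 other numbered families, so this timing stays open. Different growth of the preps for another reason was not tested.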

How the results depend on the processing

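Tests of lists without some of their members were chosen after the data were seen; the other alternatives were set in advance. The 7577 features past the threshold became 3888 with an unmoderated test (1595 higher, 2293 lower), 4213 at an adjusted p under 0.01 (1689 and 2524), 3723 with an absolute log2 ratio of at least 1 (1565 and 2158) and 2428 with treat against a fold of 1.5 (970 and 1458). The stricter criteria lower the count by construction. The unmoderated test lacks the 4.04 prior degrees of freedom that eBayes added, and how much of the fall this explains was not tested. Leaving out 1 prep gave 5156 to 6513 features, 2073 (without prep 4) to 2789 (without prep 1) of them higher, 3059 to 3724 lower; 66.3% to 78.5% of the 7577 calls were kept and 0 changed sign. With the other centring, scalings, filters and fits the count lay between 7528 and 8077. For named genes with a call, 963 of 972 values under alternatives kept call and direction, 9 lost the call (snt-1, rpl-11.2 and his-38) and 0 reversed. Of the genes without a call, vit-2 changed sign without prep 1 or 3 (-0.19 to 0.28 over the preps left out), and vit-5 kept its sign. The number of lists past the threshold fell from 18 to 0 with an estimated correlation. Camera then gave 4 lists an unadjusted p under 0.05, and estimated correlations of 0.00465 to 0.476 for those 18 lists in place of 0.01. The unadjusted camera p of the neuropeptide list rose from 1.99e-11 to 0.0059, although its estimated correlation, 0.00758, lay below 0.01. That of the X-linked list, with a correlation of 0.00465, rose from 0.00048 to 0.0161. A larger correlation was thus not the cause in these lists. With an estimated correlation, camera takes its degrees of freedom from the 4 arrays in place of the number of features. That raises p even at the same correlation. How much of the rise in p in the remaining lists came from correlated genes was not tested. In the other settings the number of lists past the threshold was 17 to 20, and 17 to 19 without 1 prep. Apart from the DAF-16 list, no list past the threshold had an adjusted p above 0.0471 in those other settings. Fry also called early embryo (adjusted p = 0.0364, alternatives up to 0.434) and heat shock genes (0.0430, up to 0.926). Among lists without a call, the test changed direction for ribosomal proteins with fry (list mean -0.0217) and without prep 3 or 4 (means -0.0794 to 0.0552 over the preps left out), for histones without prep 1 or 2 (-0.155 to 0.00566) and for heat shock genes without prep 1 (-0.354 to -0.147); the cause was not tested. In no list did the median or mean change sign under the other centring and scalings. The median correlation between preps was 0.729 by Spearman in place of 0.755, and the cause was not tested. The random blocks for shared title prefix or date were not run: with 3 blocks on 4 arrays, 0 of 200 features gave a correlation. No paired analysis was possible because there is 1 group. Signal over background, which limits the precision of dim spots, is unknown.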

Other observations

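The tests of numbered families and of neighbouring genes were chosen after the results were seen; those of sibling genes and of sign patterns were not. Among 101 numbered gene families with at least 15 tested members, some enzyme families had mostly higher ratios. Of 62 UDP-glucuronosyltransferase genes (ugt), 45 were higher and 1 lower, with a median log2 ratio of 1.21 (camera of limma, adjusted p = 6.60e-13, adjusted p = 0.687 with an estimated correlation). Of 67 cytochrome P450 genes (cyp), 34 were higher and 2 lower (median 0.61, adjusted p = 1.35e-06, adjusted p = 0.687 with an estimated correlation), and of 32 carboxylesterase genes (cest), 21 were higher and 1 lower (median 0.92, adjusted p = 8.40e-08, adjusted p = 0.687 with an estimated correlation). Of 31 glutathione transferase genes (gst), 9 were higher and 4 lower, and the family did not pass (median 0.22, adjusted p = 0.138). Subunits of the vacuolar proton pump (vha) were higher in 14 of 17 cases and lower in 1 (median 1.20, adjusted p = 3.24e-06, adjusted p = 0.687 with an estimated correlation). Among lower families, 17 of 21 nuclear pore genes (npp) were lower and 0 higher (median -0.99, adjusted p = 2.24e-06, adjusted p = 0.687 with an estimated correlation), as were 12 of 16 Skp1-related genes (skr), with 1 higher (median -0.72, adjusted p = 0.00317, adjusted p = 0.687 with an estimated correlation). Of 44 math genes, which encode a MATH domain, 25 were higher and 1 lower (median 0.74, adjusted p = 1.35e-06, adjusted p = 0.687 with an estimated correlation), and of 31 bath genes, which add a BTB domain, 16 were lower and 1 higher (median -0.69, adjusted p = 0.00102, adjusted p = 0.687 with an estimated correlation). The difference between both families was not tested. With an estimated correlation 0 of the 101 families passed in camera (4 with an unadjusted p under 0.05, lowest adjusted p = 0.535), and none of the medians named here changed sign under the other centring and scalings. That test has only the degrees of freedom of the arrays and is adjusted over 101 families. Failing it therefore does not show that a family did not differ.

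Sibling genes, which share a symbol up to the last number, more often than not moved together. Of 70 sibling pairs with both members past the threshold, 14 (20%) had opposite signs. In 95% of 10000 random re-pairings of the same genes it was 38.6% to 61.4%, so that sibling ratios moving independently is argued against. Siblings similar in sequence could be read by each other's spots, which was not tested. The widest opposite pairs, named after their values were seen, were ucr-2.3 (-2.90 ± 0.12) with ucr-2.2 (1.27 ± 0.13), slc-36.5 (-2.05 ± 0.31) with slc-36.2 (1.64 ± 0.42) and rpl-11.1 (-2.77 ± 0.03) with rpl-11.2 (0.66 ± 0.09). The ATP synthase genes asb-1 (-2.14 ± 0.19) and asb-2 (0.96 ± 0.29), which differ in the whole number and were not in that count, also went apart.

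Genes with the highest and those with the lowest ratios lay next to each other more often than random genes. Of 95 named protein-coding genes at least 8-fold higher, 10 pairs were direct neighbours, against a median of 0, an upper bound of 2 for the 95% range and a maximum of 4 in 10000 random draws of as many genes from the 14301 placed. For genes at least 8-fold lower there were 6 pairs, against a median of 1, an upper bound of 3 and a maximum of 7, so both counts lay above the bound. The higher pairs, named after their values were seen, included cld-1 (6.27 ± 0.92) with dod-21 (6.40 ± 0.94), pud-4 with pud-2.1, col-7 with col-62, ugt-43 (3.30 ± 0.72) with ugt-44 (3.29 ± 0.57), and mbug-1 with dod-17. Similar neighbouring copies could be read by each other's spots, which was not tested.

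Of the 8 ways to turn the signs of the 4 arrays against each other, 1 gave as many features past the threshold as the real 7577, the real one itself, and the highest of the others was 0. With 8 patterns the share cannot fall under 0.05.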
